A study of Homo sapiens with 8 samples.

How the data were processed

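Expression was measured on Affymetrix HG-U133A arrays, on which a gene is read by 1 or more probe sets, in 8 samples of a human non-small cell lung adenocarcinoma cell line. The groups were control, rosiglitazone, carboplatin and the combination, with 2 arrays each, taken from the sample titles in the labels. Biotinylated RNA was made with an oligo-dT primer, per the labels' protocols. The deposited values are intensity values, 1 signal per probe set on a linear scale, and the software, background correction and scaling that made them are not given in the sources used here. The values ran from 0.032 to 14940.6 over 22283 probe sets, with no detection calls in the table used. The ratio of 3' to 5' control signal was 0.83 to 1.05 for GAPDH and 0.94 to 1.39 for ACTB. The 2 arrays of a group had no identical values.

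Signals were taken as log2(signal + 16), so changes of dim probe sets are understated. The array medians on this scale spanned 0.43, more than the 0.2 set as the limit before the data were examined, so the log2 values were quantile normalized (limma 3.58.1 in R 4.3.3). The deposited scaling and median scaling were alternatives. The 68 control probe sets were left out, as were probe sets with a mean log2 value below the 40th percentile, which left 13338. In the annotation used 19071 probe sets have 1 gene symbol, 1043 have several and 2169 have none, and only those with 1 were named. Of the 19071, 19059 were found by Entrez identifier in the RefSeq gene table of GRCh38.p14, and no symbol changed. For 8030 genes the probe set with the highest mean represented the gene.

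A linear model with 1 coefficient per group was fitted to all 8 arrays with limma lmFit and eBayes with an intensity trend, which left 4 residual degrees of freedom and added 7.1 prior ones. All 8 contrasts were tested two-sided with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. They were 5 differences between pairs of groups, the interaction, and the main effect of each drug. Gene lists, 26 in number and fixed before the data were examined, were tested with camera at a preset correlation of 0.01 where at least 5 genes were tested, with adjustment over the lists within a contrast. Camera with an estimated correlation and fry were alternatives. With an estimated correlation camera tests on the 4 residual degrees of freedom, where the preset uses far more, set by the number of genes. The estimate was below the preset for some lists, at -0.0056 for sterol synthesis, -0.023 for fatty acid synthesis and -0.043 for NF-κB targets. A call lost with an estimated correlation therefore need not mean that the genes of a list are correlated. The metallothionein list is a family that the study reported on from these samples.

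Genes were named by a rule set before the data were examined. For each contrast with control these were the 10 largest rises and 10 largest falls among called genes whose 2 arrays in one group both lay beyond the 2 in the other. For other contrasts 5 and 5 were taken, and where none passed in a direction the 5 smallest p-values. Every metallothionein measured above the filter was added, with up to 4 members of smallest p from each other list.

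On simulated data with the real means and spreads of 13338 probe sets, the rosiglitazone against control contrast called 55 of 100 probe sets changed by a log2 value of 1 and 88 of 100 changed by 2, with 8 false calls. The rosiglitazone main effect called 72 of 100 and 96 of 100, with 5 false calls. For lists of 20 genes raised by 0.4 in rosiglitazone against control, camera called 10 of 10, and 0 of 10 unchanged lists. Probe sets were simulated independently of each other. The false calls of camera for lists of correlated genes, such as metallothioneins (estimated correlation 0.52), were therefore not tested.

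Alternatives set before the data were examined were the 2 other scalings, pseudocounts of 1 and 64, no filter, a filter at the 60th percentile, eBayes without a trend, only the groups compared, the replicate number as a block, and leaving out each of the 8 arrays in turn. Where that leaves a group with 1 array, the lone array is assumed to vary like the other groups. Calls of single genes were followed over up to 17 alternatives. These leave out the fit of only the groups compared and include array brightness (median log2 signal) as a covariate, chosen after seeing the data.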

Results

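Gene expression was measured in a human non-small cell lung adenocarcinoma cell line, which the labels do not name. The series title concerns synergy between ligands of PPARγ, a nuclear receptor that regulates lipid metabolism genes, and platinum drugs. Cells received the control treatment, the PPARγ ligand rosiglitazone at 1 µM, the DNA-crosslinking drug carboplatin at 10 µM, or both drugs for 24 h. Each of the 4 groups had 2 arrays, so 8 arrays were compared, and the labels do not restate the doses in the combination. The labels do not say whether the 2 arrays of a group came from separate cultures. Every limma p-value of a probe set therefore measures only the spread between these arrays, which may be technical. Camera p-values at the preset correlation compare the genes of a list with other genes, so they measure a spread across genes and not between cultures. In the deposited table the median signal of the 2 arrays was 45.8 and 36.2 in control, 46.4 and 54.3 with rosiglitazone, 37.6 and 44.6 with carboplatin, and 37.2 and 52.2 with the combination. Correlations between arrays ran from 0.964 to 0.984 across the 13338 probe sets tested, and those between the 2 arrays of a group from 0.974 to 0.976. Of the 24 pairs of arrays from different groups, 7 correlated more closely than any pair within a group, the closest being rosiglitazone 2 and combination 2 (0.984). These 7 were control 1 with carboplatin 1 and every pair among control 1, rosiglitazone 2, carboplatin 2 and combination 2. Those 4 are the arrays of higher median signal in their groups, and whether they share a batch was not tested. The small number of arrays limits the precision of every value. Changes are given as log2 differences of quantile normalized log2(signal + 16) with the standard error (SE) from limma, and n = 2 arrays per group throughout. Adjusted p-values are from limma with Benjamini-Hochberg adjustment unless camera is named.

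Rosiglitazone against control asked what the PPARγ ligand alone did to these cells. PPAR target genes were among the called rises. ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose by 2.62 ± 0.23 (6.14-fold, adjusted p = 0.000814), and PLIN2, a lipid droplet coat protein, rose by 1.67 ± 0.12 (adjusted p = 0.00025). PDK4, a kinase that restrains pyruvate oxidation, rose by 2.16 ± 0.31, and ECH1, an enzyme of fatty acid oxidation, by 0.76 ± 0.13. Of the 21 PPAR target genes tested, 17 were higher, 4 passed the threshold as rises and none as falls. Adjusted over the list alone, 12 rose and 1 fell. The list as a whole ranked higher than other genes by camera (adjusted p = 2.0e-11), also with an estimated correlation (adjusted p = 0.034 with an estimated correlation).

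Further rises passed in genes of other functions. AQP3, a water and glycerol channel, rose by 1.87 ± 0.21, and DLC1, a GTPase-activating protein gene, by 1.70 ± 0.13. FA2H, a fatty acid 2-hydroxylase, rose by 1.39 ± 0.14, KLF4, a zinc finger transcription factor, by 1.27 ± 0.20, and the calcium pump gene ATP2B4 by 1.23 ± 0.14. The ETS repressor gene ERF rose by 1.12 ± 0.18 and the death receptor gene TNFRSF21 by 1.04 ± 0.14. HMOX1, which encodes heme oxygenase, rose by 0.78 ± 0.14 and was the 1 called member of the 20 NRF2 targets tested, of which 17 were higher. AKR1C3 (0.46 ± 0.09) and AKR1C1 (0.29 ± 0.07) did not pass, and these paralogs are so alike that their probe sets may read each other's transcripts. The NRF2 list was called by camera (adjusted p = 7.4e-05), and the call was lost with an estimated correlation (adjusted p = 0.15 with an estimated correlation). The sterol synthesis list was also called upward, with 14 of 17 genes higher and none past the threshold (camera adjusted p = 0.0015, adjusted p = 0.15 with an estimated correlation). Its smallest p-values were those of SREBF2 (0.88 ± 0.21), INSIG1 (0.59 ± 0.21) and SQLE (0.36 ± 0.13). Of 11 fatty acid synthesis genes 10 were higher and none passed, led by ELOVL6 (0.69 ± 0.15) and ACLY (0.45 ± 0.17). That list had a camera adjusted p of 0.0059, which was lost with an estimated correlation (adjusted p = 0.15 with an estimated correlation). The fatty acid synthesis call was also lost with the deposited scaling (adjusted p = 0.0579), without control 2 (adjusted p = 0.0551) and without rosiglitazone 1 (adjusted p = 0.0787). Adjusted over the list alone, 5 NRF2 targets, 1 sterol synthesis gene and 1 fatty acid synthesis gene rose.

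The falls with rosiglitazone included metallothioneins, small cysteine-rich proteins that bind zinc and copper. MT1X fell by 1.06 ± 0.16 (adjusted p = 0.026), MT2A by 0.86 ± 0.12 (adjusted p = 0.020) and MT1H by 0.69 ± 0.12 (adjusted p = 0.044). MT1G (-0.77 ± 0.15), MT1F (-0.81 ± 0.17), MT1E (-0.41 ± 0.19) and MT3 (-0.31 ± 0.34) did not pass. All 7 members tested were therefore lower, 3 of them past the threshold and 5 when adjusted over the list alone, and MT3 was at 0.11 with array brightness as a covariate, a setting chosen after seeing the data. The study reported on this family from these same samples, so the list is not independent evidence of its direction. The list was called downward by camera (adjusted p = 1.5e-09), and the call was lost with an estimated correlation (adjusted p = 0.15 with an estimated correlation). Of the 10 metallothionein probe sets tested, 9 carry the mark of probes that can read several near-identical transcripts, so which members fell is uncertain. A dim second MT1G probe set and the probe sets of MT1M and MT4 were below the filter and were not tested. That MT1G probe set lacks the mark and was higher with rosiglitazone, at log2 values of 4.90 and 5.21 against 4.50 and 4.12 in control. In the same order MT1M, near the floor of the scale, was at 4.17 and 4.15 against 4.07 and 4.06, and MT4 at 4.32 and 4.27 against 4.78 and 4.22. With carboplatin alone the dim MT1G probe set was at 4.80 and 5.30, so its higher signal was not particular to rosiglitazone. Other called falls were NXN, a thioredoxin-family oxidoreductase (-1.28 ± 0.15), CXCL8, the neutrophil chemokine (-1.23 ± 0.22), and RGS2, a regulator of G protein signalling (-1.07 ± 0.17). RPS6KA5 (-1.04 ± 0.18), CSGALNACT1 (-0.93 ± 0.14), EFEMP1 (-0.91 ± 0.16) and MACF1 (-0.73 ± 0.12) also fell.

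**Figure D1:**
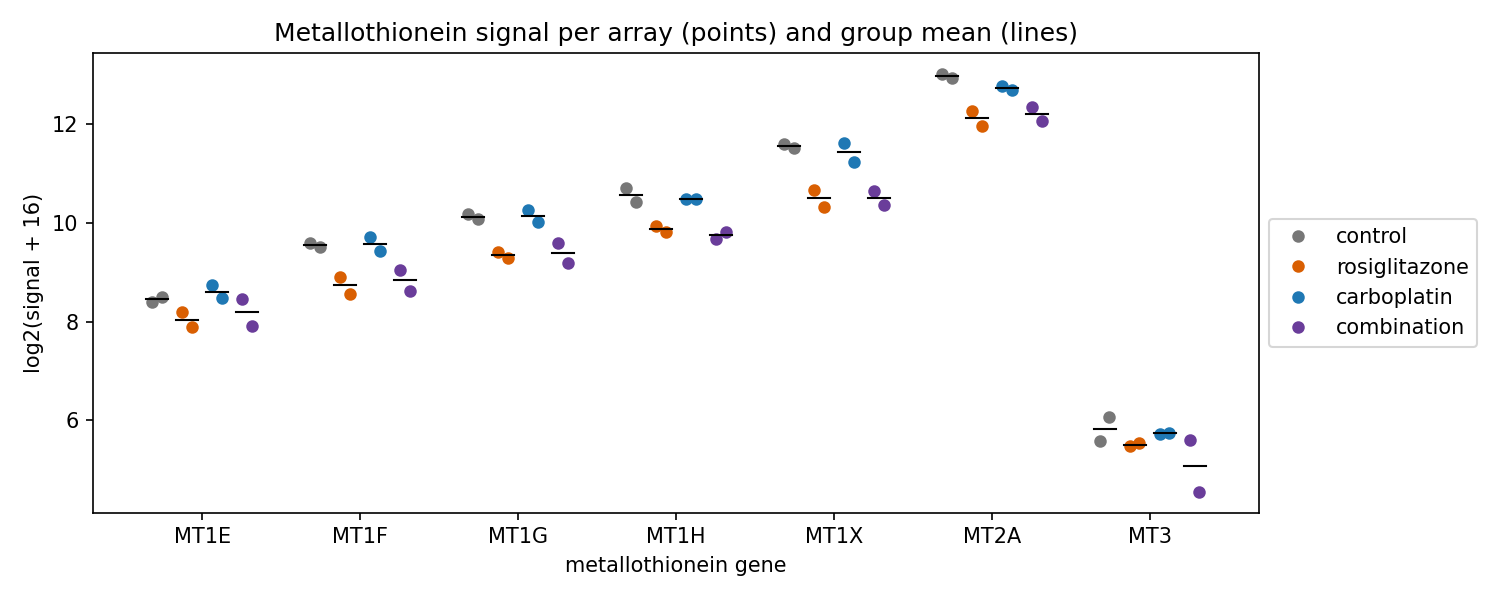
Signal of the 7 metallothionein genes tested on each array, as quantile normalized log2(signal + 16) on the vertical axis. Points are the 2 arrays of each group and lines are group means. MT1X, MT2A and MT1H lie lower on the rosiglitazone and combination arrays than on the control arrays, and the changes of MT1E and MT3 did not pass the threshold.

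In all, 48 probe sets passed the threshold, 36 higher and 12 lower. The split was 21 higher and 3 lower with the deposited scaling, under which the median of all probe sets shifted by 0.22. Of those 24, only 12 were among the 48. With median scaling the split was 14 higher and 4 lower. The count was 6 with no filter on dim probe sets, 6 without the intensity trend in eBayes, and 19 with the brightness covariate. Of that 19, only 11 were among the 48. Leaving out 1 array gave 17 without control 1, 14 without control 2, 7 without rosiglitazone 1, 3 without rosiglitazone 2 and 30 without carboplatin 2. ANGPTL4, DLC1 and PLIN2 passed under all 17 alternative settings in which each was tested. Here and below, the 17 include the brightness covariate and leave out the fit of only the groups compared, in which single genes were not followed. Every other rosiglitazone call named above was lost under at least 1 of its alternatives. MT1H passed in 3 of 17, ECH1 in 4 of 17, and both lost the call without each of the 8 arrays in turn. Sizes of dim genes depended on the pseudocount, AQP3 running from 1.04 with 64 to 2.63 with 1, PDK4 from 1.31 to 2.82 and KLF4 from 0.84 to 1.53. The change of MT1H was -0.43 with the deposited scaling.

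Carboplatin against control asked what the platinum drug alone did. Genes controlled by p53, the transcription factor activated by DNA damage, were higher. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose by 1.55 ± 0.18 (2.93-fold, adjusted p = 0.026). ERF rose by 1.54 ± 0.18 (2.90-fold, adjusted p = 0.026), and these were the only 2 probe sets past the threshold among 13338. All 26 p53 targets tested were higher, with a median of 0.42, and 1 passed. Adjusted over the list alone, 7 rose. The list was called by camera (adjusted p = 1.6e-17), also with an estimated correlation (adjusted p = 0.014 with an estimated correlation). After CDKN1A its smallest p-values were those of GDF15, a stress-induced cytokine (1.07 ± 0.16), the death receptor gene TNFRSF10B (0.51 ± 0.15) and EDA2R (0.84 ± 0.27), none of which passed over all probe sets.

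No probe set passed as lower after carboplatin. Among falls the naming rule listed ATP2C1 (-1.27 ± 0.23), FKBP2 (-0.82 ± 0.18) and ASB6 (-0.90 ± 0.20). It also listed CYBC1 (-0.70 ± 0.16) and GMEB1 (-1.29 ± 0.31), and none of these genes passed. The mitotic regulator gene CDC20 (-0.43 ± 0.10), the adhesion molecule gene ICAM1 (0.89 ± 0.24) and CXCL8 (-0.81 ± 0.22) did not pass either. Metallothionein changes ran from -0.25 ± 0.12 for MT2A to 0.16 ± 0.19 for MT1E, and none passed. Between them lay MT1X (-0.12 ± 0.16), MT1H (-0.08 ± 0.12), MT3 (-0.08 ± 0.34), MT1F (0.02 ± 0.17) and MT1G (0.02 ± 0.15). The 2 probe sets of MT1E and of MT1F differed in sign, and the values of MT1F and MT1G were negative with the deposited and the median scaling. At an unadjusted p under 0.05 there were 690 probe sets, 314 of them lower, where 666.9 would arise by chance. The count of 2 fell to 0 with the deposited scaling, with median scaling, with no filter and without the intensity trend. It was 1 with only the 2 groups compared, 1 without rosiglitazone 1 and 1 without rosiglitazone 2. It was 0 without control 1, without control 2, without carboplatin 1 and without carboplatin 2. The p53 list was called under each of the list alternatives run.

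**Figure D2:**
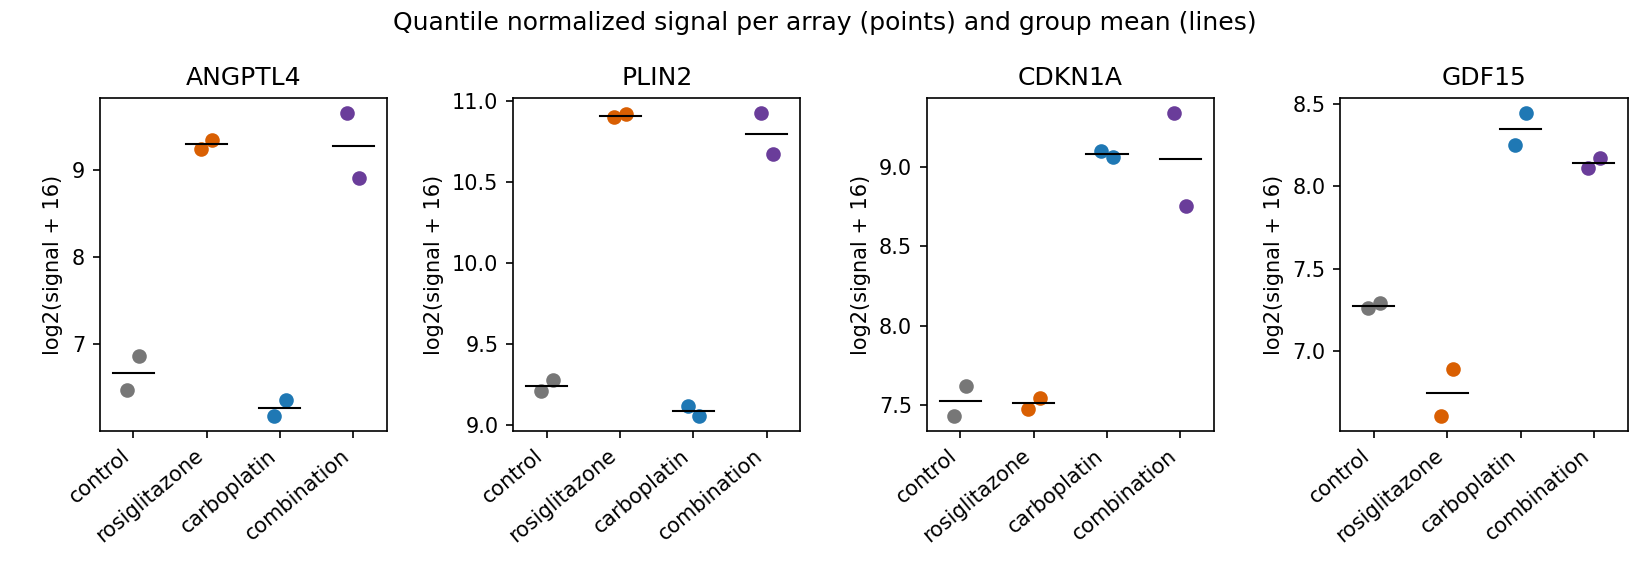
Quantile normalized log2(signal + 16) of ANGPTL4, PLIN2, CDKN1A and GDF15 on each array, with points for the 2 arrays of a group and lines for group means. ANGPTL4 and PLIN2 were higher with rosiglitazone, by 2.62 and 1.67, and CDKN1A was higher with carboplatin, by 1.55. The GDF15 change with carboplatin alone did not pass the threshold.

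Combination against control asked what both drugs together did. The PPAR and p53 target groups were both higher. ANGPTL4 rose by 2.61 ± 0.23 (6.08-fold, adjusted p = 0.000860), AQP3 by 1.94 ± 0.21, DLC1 by 1.56 ± 0.13, PLIN2 by 1.56 ± 0.12 and FA2H by 1.46 ± 0.14. CDKN1A rose by 1.52 ± 0.18 (2.86-fold, adjusted p = 0.0074) and ERF by 1.40 ± 0.18. The apolipoprotein gene APOC1 rose by 1.34 ± 0.23, ATP2B4 by 1.15 ± 0.14, with 2 of its 3 probe sets higher, and HMOX1 by 1.12 ± 0.14. Of 21 PPAR targets 16 were higher, 2 passed and 10 rose when adjusted over the list alone. ECH1 (0.73 ± 0.13) and CAT, which encodes catalase (0.80 ± 0.15), did not pass over all probe sets. Of 26 p53 targets 23 were higher, 1 passed and 5 rose when adjusted over the list alone. PHLDA3 (0.93 ± 0.17), GDF15 (0.87 ± 0.16) and TNFRSF10B (0.69 ± 0.15) did not pass. Camera called both lists (adjusted p = 2.2e-12 for PPAR targets and 1.0e-10 for p53 targets), and both calls held with an estimated correlation (adjusted p = 0.019 each).

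CXCL8 fell by 1.44 ± 0.22 (adjusted p = 0.032), CSGALNACT1 by 1.15 ± 0.14, RGS2 by 1.06 ± 0.17 and EFEMP1 by 0.94 ± 0.16. TFAP2A, a transcription factor gene, fell by 0.93 ± 0.15, and its 2 probe sets differed in sign. MT1X fell by 1.05 ± 0.16, MT1H by 0.82 ± 0.12 and MT2A by 0.78 ± 0.12. MT1G (-0.73 ± 0.15), MT1F (-0.72 ± 0.17), MT3 (-0.74 ± 0.34) and MT1E (-0.26 ± 0.19) did not pass. All 7 metallothioneins were thus lower, 3 past the threshold and 5 adjusted over the list alone, in a list the study chose on these samples, and without combination 2 MT1E was at 0.0055. Camera called it (adjusted p = 4.2e-11, lost at adjusted p = 0.096 with an estimated correlation).

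A further 7 lists were called by camera for the combination, and each of these calls was lost with an estimated correlation. For NF-κB, sterol synthesis and fatty acid synthesis genes that estimate was below the preset, so the loss there is not a sign of correlated genes. Genes of mitosis were lower in 31 of 37 cases, none past the threshold, led by CCNB2 (-0.40 ± 0.11), DLGAP5 (-0.46 ± 0.14) and CDC20 (-0.32 ± 0.10). That list had a camera adjusted p of 2.3e-05 (adjusted p = 0.20 with an estimated correlation). The DNA replication call was lost with the deposited scaling (adjusted p = 0.257), without control 1 (adjusted p = 0.0634), control 2 (adjusted p = 0.157) or combination 1 (adjusted p = 0.726). DNA replication genes were lower in 25 of 33 cases, none past the threshold, led by CHAF1A (-0.41 ± 0.15) and MCM2 (-0.25 ± 0.11), with camera adjusted p = 0.047 (adjusted p = 0.34 with an estimated correlation). NF-κB target genes were lower in 14 of 18 cases, 1 of them past the threshold, with camera adjusted p = 0.0021 (adjusted p = 0.096 with an estimated correlation). The chemokine genes CCL2 (-0.996 ± 0.19) and CXCL1 (-0.97 ± 0.26) did not pass, nor did ICAM1 (0.78 ± 0.24), whose 2 probe sets differed in sign. Adjusted over the list alone, 1 NF-κB gene rose and 5 fell. Sterol synthesis genes were higher in 16 of 17 cases, none past the threshold, including MVD (0.69 ± 0.25) and LSS (0.39 ± 0.16), with camera adjusted p = 2.3e-05 (adjusted p = 0.063 with an estimated correlation). Fatty acid synthesis genes were higher in 9 of 11 cases, none past the threshold and 2 adjusted over the list alone. ACLY (0.74 ± 0.17) and ELOVL6 (0.57 ± 0.15) did not pass over all probe sets, with probe sets of differing sign for ELOVL6, and the list had camera adjusted p = 0.0021 (adjusted p = 0.096 with an estimated correlation). NRF2 targets were higher in 15 of 20 cases, 1 past the threshold and 4 adjusted over the list alone, with camera adjusted p = 0.0062 (adjusted p = 0.20 with an estimated correlation). The NRF2 call was lost without combination 2 (adjusted p = 0.312), where the median of 0.037 became -0.029. Lung epithelial genes were higher in 8 of 12 cases, 1 past the threshold, with camera adjusted p = 0.047 (adjusted p = 0.20 with an estimated correlation). That call was lost with no filter (adjusted p = 0.0552), without control 1 (adjusted p = 0.195), combination 1 (adjusted p = 0.40) or combination 2 (adjusted p = 0.0652). Adjusted over that list alone 3 rose and 2 fell. KRT7, a keratin gene (0.59 ± 0.13), and FOXA2, a transcription factor gene of airway epithelium (-0.65 ± 0.22), did not pass over all probe sets.

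In all, 30 probe sets passed for the combination, 22 higher and 8 lower. The split was 15 higher and 1 lower with the deposited scaling, and only 7 of these 16 were among the 30. It was 12 higher and 3 lower with median scaling. The count was 12 with no filter, 46 with the stricter filter and 5 without the intensity trend. It was 10 without control 1, 12 without control 2, 11 without combination 1 and 9 without combination 2. ANGPTL4, DLC1 and PLIN2 passed in all 17 alternatives, and every other call named for the combination was lost in at least 1. AQP3 was at 1.08 with a pseudocount of 64.

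Combination against carboplatin asked what rosiglitazone added in the presence of the platinum drug. ANGPTL4 rose by 3.01 ± 0.23 (8.03-fold, adjusted p = 0.000292), PLIN2 by 1.71 ± 0.12, DLC1 by 1.60 ± 0.13, FA2H by 1.55 ± 0.14 and APOC1 by 1.53 ± 0.23. EFEMP1, which encodes an extracellular matrix protein, fell by 1.08 ± 0.16, and CSGALNACT1, a chondroitin sulfate synthesis gene, by 1.03 ± 0.14. AQP3 (1.42 ± 0.21), KLF4 (1.30 ± 0.20), HMOX1 (0.93 ± 0.14) and ECH1 (0.83 ± 0.13) also rose. Of 21 PPAR targets 18 were higher, 3 passed and 10 rose when adjusted over the list alone, while CAT (0.84 ± 0.15) did not pass. Camera called the list (adjusted p = 1.5e-12), also with an estimated correlation (adjusted p = 0.030 with an estimated correlation). All 7 metallothioneins were lower and none passed, with MT1X at -0.93 ± 0.16 and MT1H at -0.73 ± 0.12, both at adjusted p = 0.051. The others were MT1G (-0.75 ± 0.15), MT1F (-0.74 ± 0.17), MT3 (-0.66 ± 0.34), MT2A (-0.52 ± 0.12) and MT1E (-0.42 ± 0.19), with probe sets of differing sign for MT1E. Adjusted over this list alone, which the study chose on these samples, 5 fell. Camera called the metallothionein list (adjusted p = 1.5e-12, lost at adjusted p = 0.115 with an estimated correlation).

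The NF-κB list was called as lower, with 12 of 18 genes lower, none past the threshold and 3 adjusted over the list alone (camera adjusted p = 0.00035, adjusted p = 0.097 with an estimated correlation). CCL2 (-1.03 ± 0.19), CXCL5 (-1.16 ± 0.32), CXCL1 (-0.89 ± 0.26) and CXCL8 (-0.63 ± 0.22) had its smallest p-values. The mitosis list was called as lower, with 27 of 37 genes lower (camera adjusted p = 0.0035, adjusted p = 0.47 with an estimated correlation). Its median of -0.11 became 0.04 with the deposited scaling, under which the median of all probe sets shifted by 0.12 and the call was lost (adjusted p = 0.319). It was also lost without carboplatin 2 (adjusted p = 0.202) or combination 1 (adjusted p = 0.107). Sterol synthesis was called as higher, with 16 of 17 genes higher and none past the threshold (camera adjusted p = 3.7e-05, adjusted p = 0.094 with an estimated correlation), and LSS was at 0.58 ± 0.16 with probe sets of differing sign. Fatty acid synthesis was called as higher with 9 of 11 genes higher (camera adjusted p = 0.018, adjusted p = 0.17 with an estimated correlation). Lung epithelial genes were called as higher with 9 of 12 higher (camera adjusted p = 0.0035, adjusted p = 0.13 with an estimated correlation), AQP3 past the threshold and KRT7 (0.63 ± 0.13) not. The fatty acid synthesis call was lost without carboplatin 1 (adjusted p = 0.160) or combination 2 (adjusted p = 0.0797), and the lung call without carboplatin 2 (adjusted p = 0.0804) or combination 1 (adjusted p = 0.107). In all, 21 probe sets passed, 19 higher and 2 lower. The count was 9 with the deposited scaling, 8 with median scaling, 6 with no filter, 5 without the intensity trend and 5 with only the 2 groups compared. It was 8 without rosiglitazone 1, 4 without carboplatin 1, 6 without carboplatin 2, 5 without combination 1 and 7 without combination 2. ANGPTL4, PLIN2, DLC1 and FA2H passed in all 17 alternatives, and the other calls named were each lost in at least 1. With a pseudocount of 64 AQP3 was at 0.85 and KLF4 at 0.78.

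Combination against rosiglitazone asked what carboplatin added in the presence of the PPARγ ligand. CDKN1A rose by 1.53 ± 0.18 (2.89-fold) and GDF15 by 1.39 ± 0.16 (2.63-fold), both at adjusted p = 0.028. The remaining called probe set rose by 1.505 ± 0.19 and is unnamed in the table used here. Of 26 p53 targets 22 were higher, 2 passed and 12 rose when adjusted over the list alone. DDB2, a DNA damage recognition gene, was at 1.04 ± 0.17 and did not pass over all probe sets. Camera called the list (adjusted p = 1.1e-17), also with an estimated correlation (adjusted p = 0.014 with an estimated correlation). The mitosis list was called as lower, with 28 of 37 genes lower and none past the threshold (camera adjusted p = 0.0032, adjusted p = 0.53 with an estimated correlation). That call was lost with the deposited scaling (adjusted p = 0.145), under which the median of all probe sets shifted by -0.14, without rosiglitazone 2 (adjusted p = 0.375), without combination 1 (adjusted p = 0.160) and with the brightness covariate (adjusted p = 0.120). No fall passed in limma. Of 605 probe sets at an unadjusted p under 0.05, 312 were lower, where 666.9 of either sign would arise by chance. Among falls the naming rule listed EGLN1 (-1.11 ± 0.25), PLCG1 (-1.21 ± 0.27) and TNFSF8 (-1.30 ± 0.31). It also listed SPDEF (-1.20 ± 0.29) and BCAT1 (-1.24 ± 0.31), with probe sets of differing sign for SPDEF. Metallothionein changes ran from -0.43 ± 0.34 for MT3 to 0.15 ± 0.19 for MT1E, and none passed. The others were MT1H (-0.13 ± 0.12), MT2A (0.09 ± 0.12), MT1F (0.09 ± 0.17), MT1G (0.04 ± 0.15) and MT1X (0.0027 ± 0.16), and with the deposited scaling the last 4 and MT1E were negative, as was MT1X with median scaling. The 3 rises became 0 rises and 1 fall with the deposited scaling, and 2 rises and 1 fall with median scaling. The count was 0 with no filter, without the intensity trend and with only the 2 groups compared. It was also 0 without control 1, control 2, rosiglitazone 1, rosiglitazone 2 or combination 1, and 1 without combination 2.

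The interaction asked whether the effect of one drug differed in the presence of the other, on the log2 scale. No probe set passed in limma, with a smallest adjusted p of 0.313, and 796 had an unadjusted p under 0.05, where 666.9 would arise by chance. In the positive direction the naming rule listed ATP2C1 (1.56 ± 0.32), ETV4 (1.15 ± 0.30) and CDIPT (0.71 ± 0.19). In that direction it also listed DNM1 (0.85 ± 0.21) and CCDC85B (0.86 ± 0.22), each with probe sets of differing sign. In the negative direction it listed PLCG1 (-2.10 ± 0.39), ERF (-1.26 ± 0.25) and PCOTH (-1.58 ± 0.34). DCBLD2 (-1.44 ± 0.32) and BCAT1 (-1.90 ± 0.44) followed in that direction. None of these genes passed, and each was at limma adjusted p = 0.82, so the probe set at 0.313 is not among them. ERF was called with each drug alone and with both. None of the 24 lists tested was called, the lowest camera adjusted p being 0.062 for NRF2 targets, of which 16 of 20 had a negative interaction, and fry and camera with an estimated correlation also called 0. Metallothionein interactions ran from -0.35 ± 0.48 for MT3 to 0.34 ± 0.17 for MT2A. The others were MT1X (0.12 ± 0.22), MT1F (0.07 ± 0.25), MT1G (0.03 ± 0.21), MT1E (-0.0074 ± 0.27) and MT1H (-0.04 ± 0.17), with probe sets of differing sign for MT1E. MT1G was negative with the deposited scaling and MT1E positive with median scaling. The median SE of an interaction was 0.29. With the deposited scaling 3 probe sets passed, all negative, and without combination 2 camera called 1 list.

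Averaged over the presence of the other drug, rosiglitazone raised 89 probe sets and lowered 29. ANGPTL4 rose by 2.81 ± 0.16 (7.02-fold, adjusted p = 1.0e-05), PDK4 by 1.75 ± 0.22, PLIN2 by 1.69 ± 0.08, DLC1 by 1.65 ± 0.09 and AQP3 by 1.65 ± 0.15. AGR2, a protein disulfide isomerase family gene, fell by 1.02 ± 0.19, EFEMP1 by 0.995 ± 0.11, CSGALNACT1 by 0.98 ± 0.10 and CCL2 by 0.95 ± 0.13. MT1X fell by 0.99 ± 0.11, MT1F by 0.78 ± 0.12, MT1G by 0.76 ± 0.11, MT1H by 0.71 ± 0.09 and MT2A by 0.69 ± 0.08, while MT1E (-0.42 ± 0.14) and MT3 (-0.49 ± 0.24) did not pass. The metallothionein list, chosen by the study on these samples, thus had 5 of 7 members past the threshold and 6 adjusted over the list alone. Of 21 PPAR targets 18 were higher, 7 passed and 11 rose when adjusted over the list alone. Camera called 7 lists. The PPAR call (adjusted p = 6.3e-15) held with an estimated correlation (adjusted p = 0.020 with an estimated correlation), and the others were lost. Their camera adjusted p was 1.1e-13 for metallothioneins (adjusted p = 0.098 with an estimated correlation), 1.3e-06 for sterol synthesis (adjusted p = 0.058 with an estimated correlation) and 0.0011 for fatty acid synthesis (adjusted p = 0.098 with an estimated correlation). It was 0.0028 for NF-κB targets (adjusted p = 0.098 with an estimated correlation), whose median of -0.16 was above 0 with the deposited scaling, 0.0036 for NRF2 targets (adjusted p = 0.24 with an estimated correlation) and 0.00675 for mitosis (adjusted p = 0.33 with an estimated correlation). The median of the mitosis list was -0.07 and became 0.12 with the deposited scaling, under which the median of all probe sets shifted by 0.17 and the call was lost (adjusted p = 0.167). It was also lost without rosiglitazone 1 (adjusted p = 0.0538), carboplatin 2 (adjusted p = 0.0890) or combination 1 (adjusted p = 0.0671), and the NRF2 call without combination 2 (adjusted p = 0.0843) and with the brightness covariate (adjusted p = 0.125). The count of 118 was 64 with the deposited scaling, 62 higher and 2 lower, and 40 of the 64 were among the 118. It was 61 with median scaling, 47 higher and 14 lower. Most of the falls named for this main effect therefore lost the call with the deposited scaling. It was 71 with no filter, 36 without the intensity trend, 77 without control 2 and 70 without carboplatin 1. ANGPTL4, PLIN2 and DLC1 passed in all 17 alternatives, and PDK4 and AQP3 in all 16 in which they were tested, at 1.03 and 0.95 with a pseudocount of 64. EFEMP1, CSGALNACT1, CCL2 and MT1X passed in 16 of 17, MT1G and MT2A in 15, MT1H in 14 and MT1F in 12, the MT1F call being lost without control 1 and without carboplatin 1. AGR2 passed in 7 of 17, was at -0.66 with a pseudocount of 64, and lost the call without each array in turn other than rosiglitazone 2.

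Averaged in the same way, carboplatin raised 4 probe sets and lowered none. CDKN1A rose by 1.54 ± 0.13 (2.91-fold, adjusted p = 0.0017), GDF15 by 1.23 ± 0.11 (2.35-fold, adjusted p = 0.0022) and ERF by 0.91 ± 0.12, and the unnamed probe set by 1.15 ± 0.13. The ERF value averages a rise of 1.54 without rosiglitazone and a change of 0.27 ± 0.18 with it, which did not pass. Of 26 p53 targets 25 were higher, 2 passed and 15 rose when adjusted over the list alone, and DDB2 (0.69 ± 0.12) and TNFRSF10B (0.47 ± 0.10) did so on the list alone. Camera called the list (adjusted p = 5.1e-32), also with an estimated correlation (adjusted p = 0.0042 with an estimated correlation). The mitosis list was called as lower with 32 of 37 genes lower and none past the threshold (camera adjusted p = 0.00071, adjusted p = 0.59 with an estimated correlation), and the call was lost without carboplatin 1 (adjusted p = 0.0978). Among falls the naming rule listed PAK1IP1 (-0.70 ± 0.15), TFAP2A (-0.49 ± 0.10) and FAM174C (-0.48 ± 0.13). It also listed CDC20 (-0.26 ± 0.07) and GMEB1 (-0.77 ± 0.22), and no fall passed in limma. Of the 536 probe sets at an unadjusted p under 0.05, 228 were lower, where 666.9 of either sign would arise by chance. The 2 probe sets of TFAP2A differed in sign. Metallothionein changes ran from -0.26 ± 0.24 for MT3 to 0.15 ± 0.14 for MT1E, with MT1H at -0.11 ± 0.09, MT2A at -0.08 ± 0.08, MT1X at -0.06 ± 0.11, MT1F at 0.06 ± 0.12 and MT1G at 0.03 ± 0.11. None of the 7 passed, and MT1F and MT1G were negative with the deposited and the median scaling. The count was 1 with the deposited scaling, 2 with no filter and 2 without the intensity trend. CDKN1A passed in all 17 alternatives, GDF15 in 16 and ERF in 2, the ERF call being lost without each of the 8 arrays in turn. The count was 2 without control 1, control 2, rosiglitazone 1, carboplatin 1 or combination 1.

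The rosiglitazone effects without and with carboplatin share no array and could be set side by side. Across 8030 genes their log2 changes had a Pearson correlation of 0.23 and a Spearman correlation of 0.15, where genes are not independent replicates. The Pearson value was 0.138 without combination 2 and 0.354 with the brightness covariate. Of 35 genes called without carboplatin, 34 had the same sign with it, and of 20 called with it all 20 had the same sign without it. Over all 8030 genes the share with the same sign was 54.4%. It was 68.1% of the 815 genes at an unadjusted limma p under 0.05 without carboplatin. Called in both were 10 rises and 2 falls, where independent lists would share 0.054 and 0.0027. The 2 carboplatin effects, without and with rosiglitazone, had a Pearson correlation of -0.06 and a Spearman correlation of -0.07 across genes, and the Pearson value was 0.015 without rosiglitazone 1. Each carboplatin contrast called 2 genes, all with the same sign in the other, and CDKN1A was called in both. Over all 8030 genes the share with the same sign was 46.8%.

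**Figure D3:**
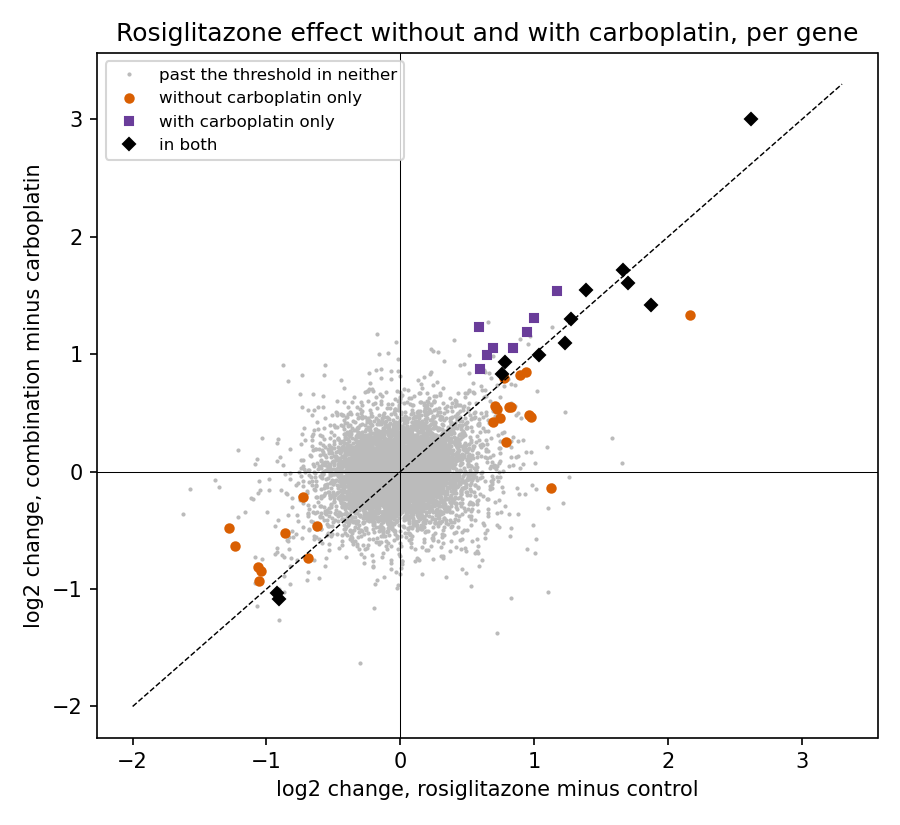
Log2 change per gene with rosiglitazone, without carboplatin on the horizontal axis and with carboplatin on the vertical axis, for 8030 genes. Black diamonds are the 12 genes called in both contrasts, coloured symbols are genes called in 1 of them, grey points are the rest and the dashed line marks equal changes. The Pearson correlation across genes was 0.23.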

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

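The test without the filter on dim probe sets was planned, and these 2 probe sets were singled out after its result was seen. They lie below the filter used for the comparisons and showed signal above the control arrays in the rosiglitazone main effect. A probe set of ELF2 rose by 1.20 ± 0.18 (SE, limma adjusted p = 0.039 without the filter). Its mean log2 values were 4.28 ± 0.05 (SD, n = 2) in control, 5.60 ± 0.38 with rosiglitazone, 4.34 ± 0.01 with carboplatin and 5.41 ± 0.30 with the combination. A dim probe set of AQP3, beside the 2 that were tested, rose by 1.10 ± 0.16 (limma adjusted p = 0.037 without the filter). Its means were 4.66 ± 0.08 in control, 5.86 ± 0.01 with rosiglitazone, 4.92 ± 0.05 with carboplatin and 5.93 ± 0.13 with the combination.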

How the results depend on the processing

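Array brightness as a covariate and the crossed block were chosen after seeing the data, and the other alternatives were set before the data were examined. Counts of probe sets past the limma threshold are given where they moved by over 1.5 times, from 48 for rosiglitazone against control, 2 for carboplatin against control, 30 for combination against control, 21 for combination against carboplatin, 3 for combination against rosiglitazone, 0 for the interaction, 118 for the rosiglitazone main effect and 4 for the carboplatin main effect. With the deposited scaling the counts were 24 for rosiglitazone against control, 0 for carboplatin against control, 16 for combination against control, 9 for combination against carboplatin, 1 for combination against rosiglitazone, 3 for the interaction, 64 for the rosiglitazone main effect and 1 for the carboplatin main effect. With median scaling they were 18 for rosiglitazone against control, 0 for carboplatin against control, 15 for combination against control, 8 for combination against carboplatin and 61 for the rosiglitazone main effect. With no filter on dim probe sets, where more were tested, they were 6 for rosiglitazone against control, 0 for carboplatin against control, 12 for combination against control, 6 for combination against carboplatin, 0 for combination against rosiglitazone, 71 for the rosiglitazone main effect and 2 for the carboplatin main effect, and the filter at the 60th percentile gave 46 for combination against control. Without the intensity trend they were 6 for rosiglitazone against control, 0 for carboplatin against control, 5 for combination against control, 5 for combination against carboplatin, 0 for combination against rosiglitazone, 36 for the rosiglitazone main effect and 2 for the carboplatin main effect. The fit of only the groups compared gave 1 for carboplatin against control, 5 for combination against carboplatin and 0 for combination against rosiglitazone. The brightness covariate gave 19 for rosiglitazone against control. The pseudocounts of 1 and 64 moved no count that far. Calls shared between the main setting and the deposited scaling were 12 for rosiglitazone against control and 7 for combination against control. They were 7 for combination against carboplatin, 0 for combination against rosiglitazone, 40 for the rosiglitazone main effect and 1 for the carboplatin main effect. The brightness covariate shared 11 with the main setting for rosiglitazone against control. Without 1 array at a time the counts ran from 3 to 49 for rosiglitazone against control, 0 to 2 for carboplatin against control, 9 to 31 for combination against control, 4 to 23 for combination against carboplatin, 0 to 3 for combination against rosiglitazone, 70 to 91 for the rosiglitazone main effect and 2 to 4 for the carboplatin main effect, and stayed at 0 for the interaction. In these fits the lone array of a group is assumed to vary like the other groups. The groups share replicate numbers, and deviations of arrays with the same number correlated at -0.0883 for control and rosiglitazone, -0.063 for control and carboplatin, -0.11 for control and combination, 0.0816 for rosiglitazone and carboplatin, 0.0942 for rosiglitazone and combination and 0.253 for carboplatin and combination, so the numbers were not taken to pair the arrays. With the replicate block the counts were 0 for carboplatin against control and 0 for combination against rosiglitazone, and 1 of 34 list calls was lost, that of DNA replication in combination against control (adjusted p = 0.0612). A crossed block for control and combination gave 15 calls, against 30. No block joined control 1 with array 2 of each other group, the brighter arrays. A batch shared by those arrays was therefore not tested.

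Camera called 5 for rosiglitazone against control, 1 for carboplatin against control, 10 for combination against control, 7 for combination against carboplatin, 2 for combination against rosiglitazone, 0 for the interaction, 7 for the rosiglitazone main effect and 2 for the carboplatin main effect, in numbers of lists. Camera with an estimated correlation called 2 for combination against control, 0 for the interaction and 1 for each other contrast. Fry called 8 for rosiglitazone against control, 1 for carboplatin against control, 10 for combination against control and 4 for combination against carboplatin. It called 1 for combination against rosiglitazone, 0 for the interaction, 8 for the rosiglitazone main effect and 1 for the carboplatin main effect. The deposited scaling and the brightness covariate each gave 1 for combination against rosiglitazone. Without 1 array the numbers ran from 4 to 6 for rosiglitazone against control, 1 for carboplatin against control, 8 to 10 for combination against control, 5 to 7 for combination against carboplatin, 1 to 2 for combination against rosiglitazone, 0 to 1 for the interaction, 6 to 9 for the rosiglitazone main effect and 1 to 4 for the carboplatin main effect. Of 34 list calls, 29 held with the deposited scaling, 33 with no filter, 32 with the brightness covariate, 24 with fry, 8 with an estimated correlation and 28 to 33 without 1 array, and none was called in the opposite direction. Of 91 calls of named genes, 28 held with the deposited scaling, 52 with median scaling, 88 and 91 with pseudocounts of 1 and 64, 41 with no filter, 31 without the intensity trend, 76 with the replicate block, 65 with the brightness covariate and 48 to 67 without 1 array. All 82 of them that passed the filter at the 60th percentile held there, and none of the 91 was called in the opposite direction under these settings. The Pearson correlation of the rosiglitazone effects with and without carboplatin was 0.226, and it was 0.179 with a pseudocount of 1, 0.289 with 64, 0.151 with no filter, 0.320 with the filter at the 60th percentile, 0.354 with the brightness covariate and 0.138 to 0.246 without 1 array. That of the carboplatin effects was -0.0625 and ran from -0.11 to 0.0146 without 1 array, above 0 without rosiglitazone 1.

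Metallothionein changes that did not pass turned sign under some settings, and the cause was not tested for these or for the counts and calls that moved, other than the larger number tested with no filter. With the deposited scaling these were MT1E (-0.0023), MT1F (-0.067), MT1G (-0.12), MT1X (-0.15) and MT2A (-0.041) in combination against rosiglitazone, MT1F (-0.068) and MT1G (-0.054) in carboplatin against control, MT1F (-0.068) and MT1G (-0.086) in the carboplatin main effect and MT1G (-0.064) in the interaction. With median scaling they were MT1E (0.060) in the interaction, MT1F (-0.073) and MT1G (-0.059) in carboplatin against control, MT1F (-0.0021) and MT1G (-0.021) in the carboplatin main effect and MT1X (-0.017) in combination against rosiglitazone. With the brightness covariate they were MT1E (-0.023), MT1F (-0.036), MT1G (-0.061) and MT1X (-0.11) in combination against rosiglitazone, MT1F (-0.061), MT1G (-0.081) and MT1H (0.015) in the interaction, MT1F (-0.0055) and MT1G (-0.020) in the carboplatin main effect and MT3 (0.11) in rosiglitazone against control. Ranges without 1 array that crossed 0 were those of MT1E (-0.54 to 0.0055) in combination against control. They were also those of MT1E (-0.12 to 0.42), MT1F (-0.12 to 0.31), MT1G (-0.17 to 0.25), MT1X (-0.18 to 0.18), MT2A (-0.069 to 0.24) and MT3 (-0.96 to 0.092) in combination against rosiglitazone. They were also those of MT1E (-0.28 to 0.26), MT1F (-0.14 to 0.29), MT1G (-0.18 to 0.23), MT1H (-0.19 to 0.10), MT1X (-0.071 to 0.31) and MT3 (-0.88 to 0.17) in the interaction. They were also those of MT1F (-0.12 to 0.16), MT1G (-0.10 to 0.14), MT1H (-0.23 to 0.062), MT1X (-0.31 to 0.073) and MT3 (-0.32 to 0.16) in carboplatin against control. They were also those of MT1F (-0.048 to 0.16), MT1G (-0.074 to 0.13), MT1X (-0.15 to 0.037) and MT3 (-0.52 to 0.0073) in the carboplatin main effect. The table used holds no detection calls, so whether a dim signal lay above background was not tested.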

Other observations

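Tests of array brightness as a covariate, of the metallothionein probe marks and of SLC30A1 were chosen after the results were seen. The gene lists and naming rule were fixed before the data were examined.

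Further genes passed in the rosiglitazone main effect over both carboplatin states. In the immediate early list KLF4 rose by 1.29 ± 0.14 (SE), JUN by 0.90 ± 0.11, KLF10 by 0.87 ± 0.16 and PHLDA1 by 0.63 ± 0.09, the 4 members past the limma threshold among 21 tested, while 13 of the 21 were lower. Adjusted over the list alone, 4 rose and 3 fell, and the list was not called (camera adjusted p = 0.75). Its median was -0.08, while its mean of 0.04 and the direction from camera were upward. In rosiglitazone against control, 2 of the 4 JUN probe sets had the opposite sign to the one given. FN1, which encodes fibronectin, rose by 0.68 ± 0.10, the transcription factor gene CEBPB by 0.47 ± 0.08, and KRT7 by 0.56 ± 0.09. HMOX1 rose by 0.86 ± 0.10, AKR1C3 by 0.39 ± 0.06 and AKR1C1 by 0.30 ± 0.05. The drug efflux transporter gene ABCG2 rose by 0.74 ± 0.12, while MGST3 (0.34 ± 0.08), a glutathione transferase gene, did not pass. ELOVL6 rose by 0.60 ± 0.11. ADM, which encodes adrenomedullin, fell by 0.54 ± 0.11, CXCL8 by 0.93 ± 0.16 and the collagen gene COL5A1 by 0.56 ± 0.10. Of these calls JUN and HMOX1 held in all 17 alternatives and KLF4 in the 16 in which it was tested, FN1 in 15 of 17 and PHLDA1 in 14, each also without any 1 array. AKR1C3, KRT7 and CEBPB held in 9 of 17, ABCG2, KLF10 and CXCL8 in 7, COL5A1 in 6, ELOVL6 in 5, AKR1C1 in 4 and ADM in 3. Without 1 array at a time, KRT7 held in 5 of 8 fits, AKR1C3 in 4, CEBPB and ABCG2 in 3, KLF10 and CXCL8 in 2, COL5A1 and ELOVL6 in 1, and AKR1C1 and ADM in 0. With the deposited scaling AKR1C1 was at 0.47, ADM at -0.35 and COL5A1 at -0.37, and with a pseudocount of 64 KLF4 was at 0.81.

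The other lists were not called by camera in the rosiglitazone main effect. The median log2 change was 0.04 for platinum transport and glutathione genes (adjusted p = 0.12), 0.05 for interferon response (adjusted p = 0.084), 0.12 for hypoxia and glycolysis (adjusted p = 0.084) and 0.10 for lung epithelium (adjusted p = 0.084). It was -0.18 for histones (adjusted p = 0.095), -0.08 for DNA replication (adjusted p = 0.10), -0.05 for the respiratory chain (adjusted p = 0.18) and -0.03 for p53 targets (adjusted p = 0.41). It was -0.01 for ATF4 and unfolded protein response genes (adjusted p = 0.41), -0.06 for crosslink repair (adjusted p = 0.45), 0.03 for apoptosis genes (adjusted p = 0.91) and 0.01 for heat shock proteins (adjusted p = 0.97). It was -0.04 for epithelial-mesenchymal genes (adjusted p = 0.80), -0.04 for metal transport and response (adjusted p = 0.69), 0.0054 for ribosomal proteins (adjusted p = 0.90) and 0.19 for the 5 fibroblast markers tested (adjusted p = 0.80). For apoptosis genes and ATF4 genes the mean and the direction from camera were opposite in sign to the median, and for heat shock proteins the direction from camera was. Leukocyte markers, with 4 genes tested, and endothelial markers, with 1, were too few for the test.

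The count of 118 probe sets in the rosiglitazone main effect was set against other splits of the arrays with a fit of 2 groups of 4. The real split called 142, and 1 of the 35 splits, the real one, called as many, the highest other count being 3. This is the smallest share that 35 splits can give, and it argues against chance if the 8 arrays are independent samples. The other splits leave the rosiglitazone effect in the spread between arrays, so the gap between 142 and 3 does not measure chance. Only 3 of the splits keep the 2 arrays of each group together, with 142, 3 and 0 calls, too few for a share under 0.05 if those arrays share a culture. The deposited median signal was 46.4, 54.3, 37.2 and 52.2 on arrays with rosiglitazone and 45.8, 36.2, 37.6 and 44.6 on those without. With array brightness as a covariate 77 of the 118 stayed past the threshold in the same direction, which argues against brightness as the whole cause of the main effect count. For rosiglitazone against control only 11 of the 48 did, so this does not extend to that contrast. For carboplatin the real split called 3, and 3 of the 35 splits called at least 3, among them the rosiglitazone split with 142. That fit leaves the rosiglitazone effect in the spread between arrays, so it does not decide whether chance gave the carboplatin count.

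The metallothionein fall with rosiglitazone was weighed against technical causes as a hypothesis. The slope of the mean metallothionein value on array brightness within groups predicts a change of -0.13 (95% interval -0.27 to 0.0094) from the brightness of the rosiglitazone arrays, where the observed mean change was -0.69. The interval lies above the larger part of the fall, which argues against brightness as the whole cause, and a smaller part may come from it. With the deposited scaling only 2 probe sets passed as lower in the rosiglitazone main effect, so most metallothionein calls were lost there. The falls of the called members kept their sign in every alternative, the smallest being -0.51 for MT1H. Only 1 of the 10 probe sets tested, that of MT3, lacks the mark of probes that read several transcripts. A test of called falls without the mark (0 found) could not decide with so few. A fall in 1 member and in several therefore cannot be told apart. The dim MT1G, MT1M and MT4 probe sets below the filter also lack the mark. Of these, the MT1G probe set was at 4.90 and 5.21 with rosiglitazone and 4.50 and 4.12 in control. It overlapped between the combination (5.72 and 5.29) and carboplatin (4.80 and 5.30). MT1M, near the floor of the scale, was at 4.17 and 4.15 with rosiglitazone against 4.07 and 4.06 in control. It overlapped between the combination (4.26 and 4.09) and carboplatin (4.08 and 4.10). MT4 did not separate rosiglitazone from control, and was at 4.53 and 4.25 with the combination against 5.44 and 4.79 with carboplatin. If less available zinc were the cause, SLC30A1, a zinc exporter gene under the same metal-responsive factor, might fall too. It was at 0.16 ± 0.12 (95% interval -0.10 to 0.43), which leaves this open, along with any other effect of the drug.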
